A study of Sus scrofa with 29 samples.

How the data were processed

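Total RNA from the colonic mucosa of 29 Ossabaw pigs was enriched for messenger RNA and made into libraries with the Illumina TruSeq RNA kit, version 2, and only RNA with a quality indicator above 8 was sequenced, per the labels' protocols. The reads were processed for quality in CLC Genomics Workbench (version not given in the sources used here) and assigned to a porcine translational research gene database, per the labels' protocols. The genome build is not given in the sources used here, so no coordinates are printed. Strand handling in counting is not given either. The deposited values are, per the file headers, counts of unique gene reads and RPKM for each of 10153 named genes in each library; the authors' RPKM divides reads by gene length and library total. The gene set is a curated database and holds part of the pig gene catalogue. Of the 10153 names, 432 end in an asterisk, 8257 match a symbol in the reference tables for assembly Sscrofa11.1 or the gene name table (6812 of the 7322 tested), and names are printed as the files give them. The ratio of RPKM to counts was nearly constant across libraries within a gene (median coefficient of variation 0.07% over 6019 genes with a mean of at least 100 reads), but varied by over 1% for 167 genes and over 5% for 33, for a reason that was not tested.

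Groups come from the labels: Western diet (named atherogenic there, n = 7), Western diet plus atorvastatin (n = 8), heart healthy diet (n = 6) and heart healthy diet plus atorvastatin (n = 8). Each library is a separate pig. Replicate numbers follow deposit order and pair nothing. The smallest chi-square per degree of freedom between any pair of libraries was 25.2, so none is another library's reads deposited again. That value says nothing on separate libraries made from 1 RNA. The file names also show library pool 1 (15 libraries) or 2 (14), with 3 and 4 libraries on the Western diet, 4 and 4 with atorvastatin added, 3 and 3 on the heart healthy diet and 5 and 3 with atorvastatin added. Sex is not given per pig in the sources used here.

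Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group (7322 genes), library sizes were scaled by TMM, and all 29 libraries entered 1 quasi-likelihood fit (estimateDisp, glmQLFit and glmQLFTest, robust) with a mean per group. The contrasts were Western minus heart healthy without and with atorvastatin, atorvastatin minus none on each diet, their interaction and both average effects. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The SE of a log2 fold change is its size divided by the square root of its F statistic. CPM values are TMM-scaled counts relative to library size.

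Gene lists, 30 in number, were fixed before the data were examined: sterol synthesis and uptake, fatty acid synthesis, sterol efflux and LXR targets, fatty acid oxidation and PPAR targets, bile acid and xenobiotic handling, short-chain fatty acid and ion transport, T cells, B cells and plasma cells, macrophages and dendritic cells, neutrophils, mast cells and eosinophils, antigen presentation, interferon response, inflammatory cytokines and NF-kB targets, goblet cells, colonocytes and junctions, enteroendocrine cells, stem cells and proliferation, smooth muscle, fibroblasts and matrix, endothelium, adipocytes, enteric neurons and glia, erythrocytes, heat shock, immediate early genes, oxidative stress and NRF2, oxidative phosphorylation, ribosomal proteins and sex chromosome genes. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values (29 lists; erythrocytes had 1 tested member), with a preset correlation of 0.01 and again with an estimated one, and adjusted over the lists of a contrast. Counts of list members are of those tested, and some lists lack most of their planned genes. Tested were 7 of 24 ribosomal protein, 6 of 25 oxidative phosphorylation, 7 of 17 neutrophil and 5 of 13 smooth muscle genes. The mean log2 CPM of a list (prior count 2) was compared between groups by an exact 2-sided permutation test.

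Named genes followed a rule fixed before the data were examined: with fewer than 10 genes past the threshold in a simple contrast or the interaction, every gene that passes and the 5 with the smallest p, plus HMGCR, HMGCS1, SQLE and LDLR in all 7 contrasts. Examples within a called list were taken from its 3 members with the smallest p, a choice made after the counts of calls were seen, as was naming the genes that other settings called. Figures for single libraries were given where leaving 1 out ended a call or moved a median, or a group mean printed in the text, by over 1.5 times, for the average contrasts only for the lists named there.

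The alternatives were RLE and upper-quartile scaling, no filter, DESeq2 1.42.0 (on all listed genes with its own filtering, leaving adjusted p undefined for 1471 genes, or 1973 for atorvastatin on the heart healthy diet), limma-voom with sample quality weights, library pool as a term, each pool alone, only the groups of a contrast, each library left out, a threshold of 0.1 and a test against a 1.2-fold change. Labels were also exchanged between groups in 100 splits per contrast, the real one included. Alternatives chosen after the data were seen were a covariate of Y-linked expression, leaving out 3 libraries high in RN7SL1, fry, permutation of list scores, all immune lists against stromal ones, the difference of the colonocyte list, and other scalings or left-out libraries for list calls. The scripts were tested on simulated counts with 200 changed genes: at 1.5-fold 56 to 62% were recovered in the simple contrasts and 20% for the interaction, at 2-fold 80 to 88% and 56%, and without planted changes at most 1 gene was called in each. Simulated genes vary independently, unlike the real ones.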

Results

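Poly(A)-selected RNA from the colonic mucosa of Ossabaw pigs, a breed prone to obesity, was sequenced from 29 animals, 1 library per pig. The study set 2 diets against each other, each fed with or without atorvastatin, an inhibitor of HMG-CoA reductase, and it concerns an interaction of dietary pattern and drug in the colon. The labels describe 32 pigs assigned at random, 16 boars and 16 gilts. The Western diet, rich in butter fat, cholesterol and refined carbohydrate, was given alone to 7 of the sequenced pigs and with atorvastatin to 8. The heart healthy diet, rich in unsaturated oils, whole grain, fruit, vegetables and fiber, was given alone to 6 pigs and with atorvastatin to 8. Both diets supplied 38% of energy as fat, 47% as carbohydrate and 15% as protein for 6 months, and pigs on the heart healthy diet also received a 1000 mg fish oil capsule 3 times per week. The drug dose was 20 mg per day in the earlier months and 40 mg per day in the later ones. Groups are abbreviated WD and WD+S for the Western diet without and with atorvastatin, and HHD and HHD+S for the heart healthy diet without and with it, and a number after the group names the replicate.

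Libraries held 10531370 to 21349602 unique gene reads (15580292 ± 2519367, SD, n = 29) over 10153 listed genes, of which 7322 had enough reads to be tested. Group means were 15691940 ± 2646372 (SD, n = 7) on the Western diet and 15251472 ± 1489092 (SD, n = 8) with atorvastatin added. They were 15815940 ± 3832275 (SD, n = 6) on the heart healthy diet and 15634682 ± 2547817 (SD, n = 8) with atorvastatin added. Mitochondrial genes took 14.1 ± 1.47% of reads (SD, n = 29). The biological coefficient of variation between pigs of a group was 27%. The first principal component of log2 CPM held 19.7% of the variance and placed HHD 6 at its far end (score -51.7), followed by WD 7 (-32.9) and HHD+S 8 (-28.2). Y-linked genes exceeded 10 CPM in 14 of the 29 libraries, spread over the groups as 3 of 7, 4 of 8, 3 of 6 and 4 of 8. The file names place the libraries in 2 pools, and 22 genes differed between the pools past an edgeR adjusted p of 0.05. Each group had libraries in both pools, so every comparison was also made within each pool.

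Across the 7 contrasts of the design, 0 genes passed an adjusted p of 0.05 in edgeR, and the differences described below are therefore those of gene lists and of the genes with the smallest p. List calls come from camera with a preset correlation between genes of 0.01. With group labels exchanged at random, this test still called a median of 8 to 9 lists, depending on the contrast. Its adjusted p therefore overstates the evidence against chance. With the correlation estimated from the data, 0 lists passed in any contrast, and that p is given beside each call described. For the average effects, only some of the called lists are described. In simulated counts with the same means, spread and library sizes, edgeR recovered 80 to 88% of genes changed 2-fold and 92 to 100% of genes changed 4-fold in the 4 simple contrasts, with 50 genes per fold size. For the interaction the shares were 56% and 82%. At 1.5-fold 56 to 62% were recovered in the simple contrasts and 20% for the interaction. Simulated genes vary independently, unlike the real ones, and without planted changes 0 lists were called. The shares may therefore not hold for the real data.

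**Figure D1:**
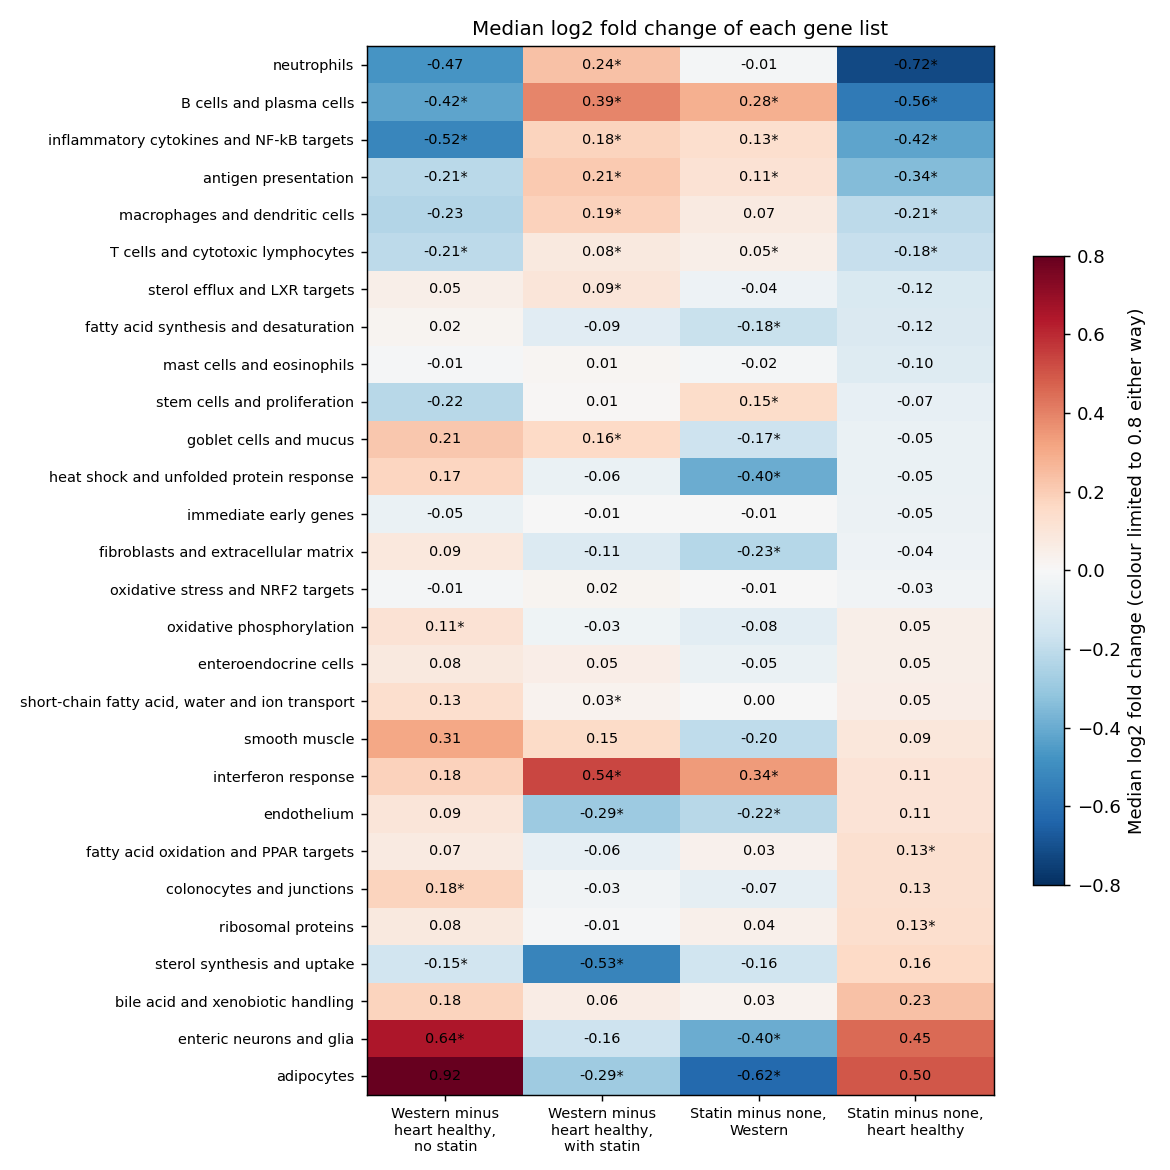
Median log2 fold change of each gene list (rows) in the 4 simple contrasts (columns), coloured from blue (lower) to red (higher); an asterisk marks a camera adjusted p under 0.05 with the preset correlation. T cell, B cell, macrophage, antigen presentation and inflammatory lists are lower in the outer 2 columns and higher in the middle 2. The outer 2 columns share the heart healthy libraries, and the middle 2 the Western plus atorvastatin libraries. Columns that share a group are not independent. Neutrophils are at -0.72 for atorvastatin on the heart healthy diet and at -0.01 for atorvastatin on the Western diet.

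Without atorvastatin, inflammatory, B cell, T cell and antigen presentation lists were called lower, and the colonocyte list higher, in colonic mucosa from pigs on the Western diet than from pigs on the heart healthy diet. Not called were the macrophage (21 of 25 lower, median -0.23, camera adjusted p = 0.0543), neutrophil (6 of 7 lower, -0.47, adjusted p = 0.07) and interferon lists (20 of 36 higher, 0.18, adjusted p = 0.775). Nor were the epithelial lists of stem cells and proliferation (13 of 18 lower, -0.22, adjusted p = 0.0546), goblet cells (9 of 12 higher, 0.21, adjusted p = 0.0734) and enteroendocrine cells (7 of 11 higher, 0.08, adjusted p = 0.327). Of 36 inflammatory cytokines and NF-kB targets, 34 were lower, with a median log2 fold change of -0.52 (camera adjusted p = 2.63e-09, adjusted p = 0.459 with an estimated correlation). NOS2, the inducible nitric oxide synthase, averaged 91.7 ± 76.9 CPM (SD, n = 7) against 356 ± 440 CPM (SD, n = 6; 187.23 CPM without HHD 6), and the chemokine CCL4 averaged 14.6 ± 2.68 against 30.5 ± 22.7 CPM. B cell and plasma cell genes were lower in 24 of 25 cases (median -0.42, adjusted p = 3.63e-06, adjusted p = 0.459 with an estimated correlation). Among them were IRF4, a transcription factor of plasma cells (log2 fold change -0.60, SE 0.19), and IGHM, the IgM heavy chain (-0.70, SE 0.30). T cell genes were lower in 30 of 34 cases (median -0.21, adjusted p = 1.42e-06, adjusted p = 0.459 with an estimated correlation). They included the costimulatory receptor CD28 (-0.59, SE 0.21) and the checkpoint receptor CTLA4 (-1.02, SE 0.38). Antigen presentation genes were lower in 23 of 25 cases (median -0.21, adjusted p = 0.000444, adjusted p = 0.639 with an estimated correlation). Within pools 1 and 2 the medians were -0.58 and -0.54 for inflammatory genes and -0.24 and -0.45 for B cell genes. They were -0.24 and -0.26 for T cell genes and -0.35 and -0.03 for antigen presentation, whose direction in camera turned in pool 2 and whose call ended there (adjusted p = 0.853). The inflammatory median was -0.29 without HHD 6 and the B cell median -0.12 without HHD 4. The antigen presentation median was -0.08 without HHD 2, which also ended that call (adjusted p = 0.0982).

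Colonocyte and junction genes lay in the other direction in the same contrast, with 18 of 23 higher on the Western diet (median 0.18, adjusted p = 0.000393, adjusted p = 0.459 with an estimated correlation). The keratins KRT19 (log2 fold change 0.38, SE 0.12) and KRT8 (0.33, SE 0.12) and the peptide guanylin, GUCA2A (0.79, SE 0.34), were its members with the smallest p. All 10 enteric neuron and glia genes were higher (median 0.64, adjusted p = 0.000393, adjusted p = 0.459 with an estimated correlation). Of these, 1, the glial filament gene GFAP (1.05, SE 0.34), was past 0.05 when adjusted over the list alone. Adipocyte (5 of 7 higher, median 0.92, adjusted p = 0.0695) and smooth muscle lists (4 of 5 higher, 0.31, adjusted p = 0.0546) were not called. WD 2 and WD 6 were the highest WD libraries for the neuronal gene VIP (287.87 and 170.69 CPM, others up to 41.74) and the adipocyte gene ADIPOQ (30.77 and 31.12 CPM, others up to 12.61), genes picked here after their values were seen. The 6 tested oxidative phosphorylation genes, of 25 planned, were all slightly higher (median 0.11, adjusted p = 0.0365, adjusted p = 0.639 with an estimated correlation). Of 23 sterol synthesis and uptake genes, 20 were lower (median -0.15, adjusted p = 0.00641, adjusted p = 0.641 with an estimated correlation). In pools 1 and 2 the medians were 0.20 and 0.15 for colonocytes, 0.92 and 0.46 for neurons and 0.19 and 0.05 for oxidative phosphorylation. Sterol genes had 0.12 and -0.40, so that their direction turned in pool 1, where the call ended (adjusted p = 0.592). In pool 2 the colonocyte (adjusted p = 0.0602), neuron (0.0602) and oxidative phosphorylation calls (0.321) ended. The colonocyte median was 0.11 without HHD 3 and the neuronal median 0.37 without WD 6. Leaving out WD 2 and WD 6 together was not tested. The oxidative phosphorylation call ended without WD 3, WD 7, HHD 1, HHD 4 or HHD 5, at adjusted p up to 0.154. The sterol call ended without WD 2, WD 4, WD 5 or HHD 6 (medians -0.09, -0.04, -0.09 and 0.02, adjusted p up to 0.477), and its median was -0.33 without WD 3 and -0.25 without HHD 5.

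In edgeR 0 of 7322 genes passed for this contrast, with 445 at an unadjusted p under 0.05. The nominal count is 366.1, and 38 of 100 splits of the labels, the real one included, reached 445. Neither DESeq2 nor limma-voom with sample weights called any (0 and 0). The genes with the smallest p, none past the threshold, included SLAMF1, a lymphocyte receptor (log2 fold change -0.50, SE 0.11, adjusted p = 0.461), and SERPINB5, an epithelial serpin (0.65, SE 0.16, adjusted p = 0.461). The others were RN7SL1 (-7.64, SE 1.87), POLR2JL* (-7.63, SE 1.88) and LOC110257199 (-2.54, SE 0.63), each with adjusted p = 0.461. The RN7SL1 and POLR2JL* differences come from HHD 1 and HHD 5, and LOC110257199 was at 27.73 CPM in HHD 5 against at most 2.58 CPM in the others of that group. Without HHD 5 the log2 fold changes of RN7SL1, POLR2JL* and LOC110257199 were -3.17, -3.05 and -0.85. SLAMF1 averaged 12.6 ± 2.24 CPM (SD, n = 7) on the Western and 17.8 ± 2.53 CPM (SD, n = 6) on the heart healthy diet. HMGCR, the target of atorvastatin, had a log2 fold change of 0.05 (SE 0.16), HMGCS1 -0.33 (SE 0.38), SQLE -0.35 (SE 0.40) and LDLR 0.13 (SE 0.36), with edgeR adjusted p of 0.971, 0.897, 0.895 and 0.964. Leaving out WD 1 gave 1 gene past the threshold, SLAMF1 (adjusted p = 0.0295), and leaving out WD+S 1 gave 3, RN7SL1, POLR2JL* and PPP2R5E. Among exact 2-sided permutation tests of list means, the colonocyte list had p = 0.0408 and the inflammatory list p = 0.0781, and the smallest after adjustment over the 29 lists was 0.722.

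With atorvastatin in both arms, diet differences were called for 13 lists, cholesterol synthesis among them. All 23 sterol synthesis and uptake genes were lower on the Western diet (median log2 fold change -0.53, camera adjusted p = 4.82e-17, adjusted p = 0.151 with an estimated correlation). MSMO1 and CYP51A1, which remove methyl groups from lanosterol-derived sterols, had log2 fold changes of -0.69 (SE 0.24) and -0.57 (SE 0.21), and SC5D, a sterol desaturase, had -0.55 (SE 0.20). MSMO1 averaged 123 ± 28.0 CPM (SD, n = 8) against 198 ± 62.0 CPM (SD, n = 8). HMGCR averaged 369 ± 43.1 against 445 ± 101 CPM (log2 fold change -0.27, SE 0.15, adjusted p = 1). HMGCS1, the enzyme before it in the pathway, had -0.66 (SE 0.34), the squalene epoxidase SQLE -0.69 (SE 0.36) and the LDL receptor LDLR -0.65 (SE 0.32), all with adjusted p = 1. Without HHD+S 8 the list's median was -0.29. It was -0.17 within pool 1 and -0.96 within pool 2. In exact 2-sided permutation tests of list means, sterol genes had p = 0.0326, endothelial genes p = 0.0241, antigen presentation p = 0.0339 and neutrophil genes p = 0.0356. The smallest exact p after adjustment over the 29 lists was 0.258.

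**Figure D2:**
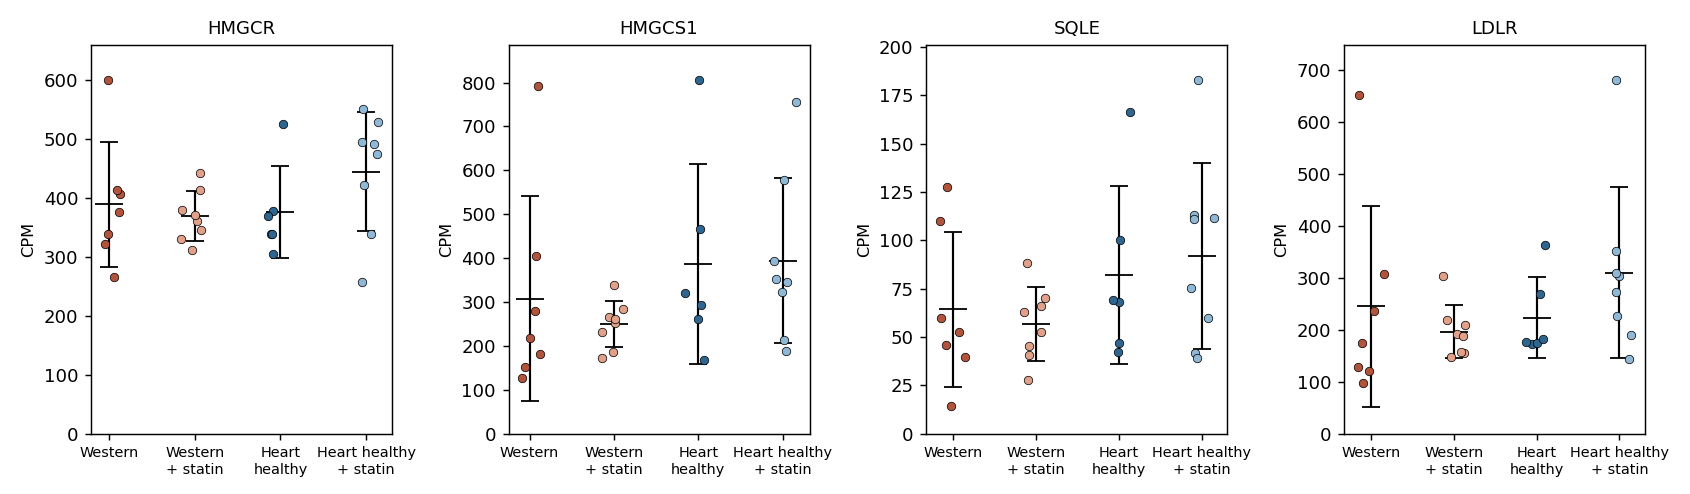
CPM (vertical axis, from 0) of HMGCR, HMGCS1, SQLE and LDLR in each of the 29 libraries (points) by group, with group mean and SD (bars). The 4 groups overlap in every panel, and HMGCR averages 389, 369, 376 and 445 CPM from left to right.

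Among atorvastatin-treated pigs, 7 immune lists were called higher on the Western diet. B cell genes were higher in 24 of 25 cases (median 0.39, adjusted p = 4.52e-11, adjusted p = 0.152 with an estimated correlation). Among them were PAX5, a transcription factor of B cells (log2 fold change 1.83, SE 0.75; HHD+S mean 5.20 CPM, 3.42 without HHD+S 1), and AICDA, the deaminase of antibody diversification (1.46, SE 0.63). All 25 antigen presentation genes were higher (median 0.21, adjusted p = 5.41e-11, adjusted p = 0.19 with an estimated correlation), including the peptide transporter genes TAP1 (0.43, SE 0.21) and TAP2 (0.29, SE 0.13). Interferon response genes were higher in 35 of 36 cases (median 0.54, adjusted p = 5.37e-08, adjusted p = 0.426 with an estimated correlation). CXCL11, a chemokine induced by interferon, was the 1 member past 0.05 adjusted over the list alone. Without WD+S 8 the interferon median was -0.08 and the call ended (adjusted p = 0.11). Inflammatory genes were higher in 29 of 36 cases (median 0.18, adjusted p = 1.79e-06, adjusted p = 0.321 with an estimated correlation). Their medians were 0.07, 0.28, 0.11, 0.12 and 0.38 without WD+S 5, WD+S 7, WD+S 8, HHD+S 1 and HHD+S 2. Macrophage and dendritic cell genes were higher in 20 of 25 cases (median 0.19, adjusted p = 0.000248, adjusted p = 0.321 with an estimated correlation). Their median was 0.09 without WD+S 8 and their call ended without HHD+S 8 (adjusted p = 0.104). Neutrophil genes were higher in 7 of 7 cases (median 0.24, adjusted p = 0.00328, adjusted p = 0.176 with an estimated correlation; 0.36 without HHD+S 5). T cell genes were higher in 24 of 34 cases (median 0.08, adjusted p = 0.00654, adjusted p = 0.583 with an estimated correlation). Their medians were 0.05, 0.14, 0.03, 0.05 and 0.13 without WD+S 5, WD+S 7, WD+S 8, HHD+S 6 and HHD+S 8, and the call ended without WD+S 2, WD+S 5, WD+S 8, HHD+S 6 or HHD+S 7 (adjusted p up to 0.158). By pool (1 and 2), medians were 0.07 and 0.70 for B cells, 0.13 and 0.35 for antigen presentation, 0.29 and 0.46 for interferon genes, 0.14 and 0.50 for neutrophils and 0.03 and 0.19 for T cells. The inflammatory (-0.08 and 0.53) and macrophage (-0.06 and 0.46) medians turned in pool 1. Calls ended in pool 1 for T cells (adjusted p = 0.206), B cells (0.0583), macrophages (0.995), neutrophils (0.0893) and inflammatory genes (0.656), and in pool 2 for interferon genes (0.127).

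All 13 endothelial genes were lower on the Western diet in these pigs (median -0.29, adjusted p = 8.3e-09, adjusted p = 0.151 with an estimated correlation). The adhesion molecule PECAM1 averaged 103 ± 11.3 against 132 ± 34.1 CPM (SD, n = 8 each). All 7 adipocyte genes were lower too (median -0.29, adjusted p = 0.00397, adjusted p = 0.321 with an estimated correlation). Their median was -0.15 without WD+S 3, -0.68 without WD+S 5 and -0.15 without HHD+S 6, which ended the call (adjusted p = 0.0752). Of 14 sterol efflux genes and targets of the oxysterol receptor LXR, 10 were higher (median 0.09, adjusted p = 0.0452, adjusted p = 0.263 with an estimated correlation). The transporter ABCG1 (0.59, SE 0.18) was the 1 member past 0.05 adjusted over the list alone. That call ended without any 1 of WD+S 1, 5, 6, 7 or 8 or HHD+S 2, 4, 5, 6 or 8 (adjusted p up to 0.202), and the median was 0.04 without WD+S 5 and 0.05 without WD+S 7. Goblet cell genes were higher in 9 of 12 cases (median 0.16, adjusted p = 0.032, adjusted p = 0.426 with an estimated correlation). Their call ended without any 1 of WD+S 1, 3 or 7 or HHD+S 2, 3, 5 or 7 (adjusted p up to 0.44). The medians were 0.04, 0.06, 0.08, 0.10 and 0.24 without WD+S 3, WD+S 7, HHD+S 5, HHD+S 7 and HHD+S 8. Genes of short-chain fatty acid, water and ion transport were called higher (11 of 19 higher, median 0.03, adjusted p = 0.0266, adjusted p = 0.321 with an estimated correlation), although their mean log2 fold change was -0.08. This call ended without WD+S 7, HHD+S 3 or HHD+S 8 (adjusted p up to 0.375), and the median, close to 0, lay between -0.01 without HHD+S 3 and 0.09 without HHD+S 2, moving by over 1.5 times without most libraries. The medians in pools 1 and 2 were -0.20 and -0.31 for endothelium, -1.02 and -0.12 for adipocytes, 0.00 and 0.16 for sterol efflux, 0.19 and 0.12 for goblet cells and -0.02 and 0.16 for transport genes. Calls ended in pool 1 for sterol efflux (adjusted p = 0.995) and transport (0.52) and in pool 2 for transport (0.143), goblet cells (0.787) and adipocytes (0.337).

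For this contrast 0 genes passed in edgeR and 192 had an unadjusted p under 0.05, fewer than the nominal count of 366.1. Of 100 splits of the labels, the real one included, 89 reached 192. DESeq2 called 2, CLEC4G and CXCL11, and limma-voom 0. CLEC4G, a C-type lectin, had the smallest p (log2 fold change 4.94, SE 0.96, adjusted p = 0.127), but it reached 33.0 CPM in WD+S 5, against at most 3.96 CPM in the others of that group, and averaged 0.182 CPM in HHD+S, near the level of 3 reads in a library. Without WD+S 5 the log2 fold change of CLEC4G was 3.40. Without WD+S 2 it was the 1 gene past the threshold in edgeR (adjusted p = 0.0432). CXCL11 (1.95, SE 0.48, and 1.14 without WD+S 8), the cytochromes CYP2S1 (-0.40, SE 0.10) and CYP1A1 (-1.5, SE 0.40) and the bradykinin receptor BDKRB2 (-0.53, SE 0.14) followed, all with adjusted p = 1.

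On the Western diet, heat shock, endothelial, fibroblast, neuron, adipocyte, fatty acid synthesis and goblet cell lists were called lower with atorvastatin, and the smooth muscle list (4 of 5 lower, median -0.20, adjusted p = 0.377) was not called. All 18 genes of the heat shock and unfolded protein response were lower with the drug (median log2 fold change -0.40, camera adjusted p = 8.53e-09, adjusted p = 0.349 with an estimated correlation). The chaperone gene HSPH1 averaged 255 ± 172 CPM (SD, n = 8) against 578 ± 405 CPM (SD, n = 7), and the co-chaperone BAG3 had a log2 fold change of -1.01 (SE 0.32) and HSP90AA1 -0.85 (SE 0.32). All 13 endothelial genes (median -0.22, adjusted p = 9.85e-06, adjusted p = 0.349 with an estimated correlation) and all 16 fibroblast and matrix genes (-0.23, adjusted p = 0.000196, adjusted p = 0.607 with an estimated correlation) were lower. So were all 10 enteric neuron and glia genes (-0.40, adjusted p = 0.00708, adjusted p = 0.607 with an estimated correlation) and all 7 adipocyte genes (-0.62, adjusted p = 0.0102, adjusted p = 0.607 with an estimated correlation). Fatty acid synthesis genes were lower in 13 of 15 cases (median -0.18, adjusted p = 0.00317, adjusted p = 0.349 with an estimated correlation). Among them was ACACA, which makes malonyl-CoA (log2 fold change -0.27, SE 0.10). Goblet cell genes were lower in 8 of 12 cases (-0.17, adjusted p = 0.0209, adjusted p = 0.607 with an estimated correlation), with the mucin gene MUC2 at 1486 ± 564 against 1991 ± 575 CPM. Pools 1 and 2 gave medians of -0.37 and -0.46 for heat shock genes, -0.26 and -0.28 for endothelium, -0.08 and -0.47 for fibroblasts and -0.41 and -0.35 for neurons. They gave -1.64 and -0.07 for adipocytes, -0.24 and -0.13 for fatty acid synthesis and -0.24 and -0.08 for goblet cells. The fibroblast call ended in pool 1 (adjusted p = 0.374). In pool 2 the neuron (adjusted p = 0.747), fatty acid synthesis (0.407), goblet cell (0.227) and adipocyte calls (0.899) ended, and the adipocyte direction in camera turned. Without WD 6 the fibroblast median was -0.08, the neuronal median -0.15 and the adipocyte median -0.36. The neuronal call ended without WD 2 or WD 6 (adjusted p up to 0.385). As said above, WD 2 and WD 6 were the highest WD libraries for VIP and ADIPOQ. They were not left out together, so their joint part in the neuron, adipocyte and fibroblast differences was not tested. The adipocyte call ended without WD 2, WD 6 or WD+S 1 (adjusted p up to 0.112), its median being -1.03 without WD+S 5. The fatty acid synthesis call ended without WD 3 (median -0.09, adjusted p = 0.106). The goblet cell call ended without WD 1, 3 or 7 or WD+S 2, 5 or 8 (adjusted p up to 0.116), with medians of -0.10 without WD+S 5 and -0.30 without WD+S 7.

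Called higher with the drug on this diet were 5 immune lists and the proliferation list. Macrophage (20 of 25 higher, median 0.07, adjusted p = 0.11) and neutrophil lists (3 of 7 higher, -0.01, adjusted p = 0.943) were not called. B cell genes were higher in 23 of 25 cases (median 0.28, adjusted p = 0.000338, adjusted p = 0.607 with an estimated correlation; 0.16 without WD+S 5). Interferon response genes were higher in 35 of 36 cases (median 0.34, adjusted p = 0.000338, adjusted p = 0.66 with an estimated correlation). The interferon median was -0.15 without WD+S 8, where the call ended (adjusted p = 0.862), and 0.85 without WD 7. Antigen presentation genes (25 of 25 higher, median 0.11, adjusted p = 0.00127) and inflammatory genes (26 of 36, median 0.13, adjusted p = 0.00493) were called, each with adjusted p = 0.66 with an estimated correlation. Stem cell and proliferation genes (16 of 18, median 0.15, adjusted p = 0.00493) and T cell genes (28 of 34, median 0.05, adjusted p = 0.0223) followed, each with adjusted p = 0.66 with an estimated correlation. The chemokine CCL2 averaged 69.1 ± 21.8 CPM (SD, n = 8) against 42.7 ± 13 CPM (SD, n = 7). The antigen presentation call ended without WD 2, WD 3 or WD+S 8 (medians 0.05, 0.07 and 0.06, adjusted p up to 0.0854), and its median was 0.19 without WD 1. The inflammatory call ended without WD 1, WD 2, WD+S 5 or WD+S 8 (adjusted p up to 0.142). The medians were 0.08, 0.05 and 0.06 without WD 2, WD+S 5 and WD+S 8 and 0.25 and 0.21 without WD 7 and WD+S 7. The proliferation median was 0.10 without WD 3 and 0.24 without WD 7. The T cell call ended without any 1 of WD 2 to 6 or WD+S 1, 2, 5 or 8 (adjusted p up to 0.345). The list had medians of 0.17, 0.02, 0.14, 0.07 and 0.11 without WD 1, WD 6, WD 7, WD+S 4 and WD+S 7. In each pool (1 and 2) the medians were 0.12 and 0.34 for B cells, 0.24 and 0.48 for interferon genes and 0.07 and 0.16 for antigen presentation. They were 0.31 and 0.10 for inflammatory genes, 0.14 and 0.16 for proliferation and 0.00 and 0.13 for T cells. The T cell call ended in pool 1 (adjusted p = 0.701) and the inflammatory (0.679) and proliferation calls (0.0701) in pool 2.

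Sterol genes were not called on the Western diet: HMGCR had a log2 fold change of -0.08 (SE 0.15), HMGCS1 -0.30 (SE 0.35), SQLE -0.18 (SE 0.37) and LDLR -0.32 (SE 0.33), all with adjusted p = 1. All 4 signs turned without WD 3 (0.06, 0.14, 0.08 and 0.15). In edgeR 0 genes passed, with 218 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 and 0. The 5 genes with the smallest p, all with adjusted p = 1, were PI16, a fibroblast gene (-1.99, SE 0.52), the butyrophilin BTN2A2 (0.71, SE 0.20), the Golgi adaptor GGA1 (-0.29, SE 0.09), the calcium pump ATP2A2 (-0.25, SE 0.08) and the chemokine CXCL14 (-0.43, SE 0.13). PI16 was high in WD 2 (65.56 CPM) and WD 6 (70.4 CPM), while the other 5 WD libraries (4.66 to 10.33 CPM) lay within or near the range of WD+S (3.21 to 8.82 CPM). In exact 2-sided permutation tests of list means, fatty acid synthesis had p = 0.0356 and heat shock genes p = 0.0723, and the smallest after adjustment over the 29 lists was 0.785.

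On the heart healthy diet, 6 immune and inflammatory lists were called lower with atorvastatin, and the interferon list (22 of 36 higher, median 0.11, adjusted p = 0.357) was not called. The HHD libraries also enter the diet difference without atorvastatin, so the lower immune lists in the 2 contrasts are not independent results. Inflammatory cytokines and NF-kB targets were lower in 32 of 36 cases (median log2 fold change -0.42, camera adjusted p = 2.18e-10, adjusted p = 0.283 with an estimated correlation). When adjusted over the list alone, 2 of them passed. SAA3, an acute phase protein, averaged 6.01 ± 4.09 CPM (SD, n = 8) against 59.9 ± 82.7 CPM (SD, n = 6; 28.02 CPM without HHD 6; edgeR log2 fold change -3.33, SE 0.76, adjusted p = 0.153). NOS2 averaged 53.3 ± 52.2 against 356 ± 440 CPM, and 187.23 CPM in HHD without HHD 6. Neutrophil genes were lower in 6 of 7 cases (median -0.72, adjusted p = 0.000648, adjusted p = 0.281 with an estimated correlation). Past 0.05 adjusted over the list alone were 4 of them, including the G-CSF receptor CSF3R (-2.05, SE 0.48; HHD mean 19.73 CPM, 12.28 without HHD 6) and the chemokine receptor CXCR2 (-1.28, SE 0.40). B cell genes were lower in 24 of 25 cases (median -0.56, adjusted p = 4.56e-09, adjusted p = 0.283 with an estimated correlation), with 2 past 0.05 adjusted over the list alone. IGHM averaged 1042 ± 419 against 1975 ± 729 CPM. All 25 antigen presentation genes were lower (median -0.34, adjusted p = 8.22e-07, adjusted p = 0.535 with an estimated correlation). So were 29 of 34 T cell genes (median -0.18, adjusted p = 4.52e-06, adjusted p = 0.535 with an estimated correlation) and 19 of 25 macrophage and dendritic cell genes (median -0.21, adjusted p = 0.00358, adjusted p = 0.623 with an estimated correlation). Granzyme A, GZMA, a product of cytotoxic lymphocytes, had a log2 fold change of -1.06 (SE 0.31), and interferon gamma, IFNG, had -1.25 (SE 0.41). Without HHD 6 the inflammatory median was -0.27 and the neutrophil median -0.45. Without HHD+S 2 the inflammatory median was -0.67, and without HHD 2 the antigen presentation median was -0.17. The macrophage call ended without HHD 2 (median -0.10) or HHD+S 8 (adjusted p up to 0.107), and its median was -0.32 without HHD 5 and -0.36 without HHD 6. Medians by pool (1 and 2) were -0.09 and -0.92 for inflammatory genes, -0.46 and -1.17 for neutrophils and -0.28 and -0.86 for B cells. They were -0.48 and -0.32 for antigen presentation, -0.31 and -0.20 for T cells and -0.30 and -0.31 for macrophages.

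**Figure D3:**
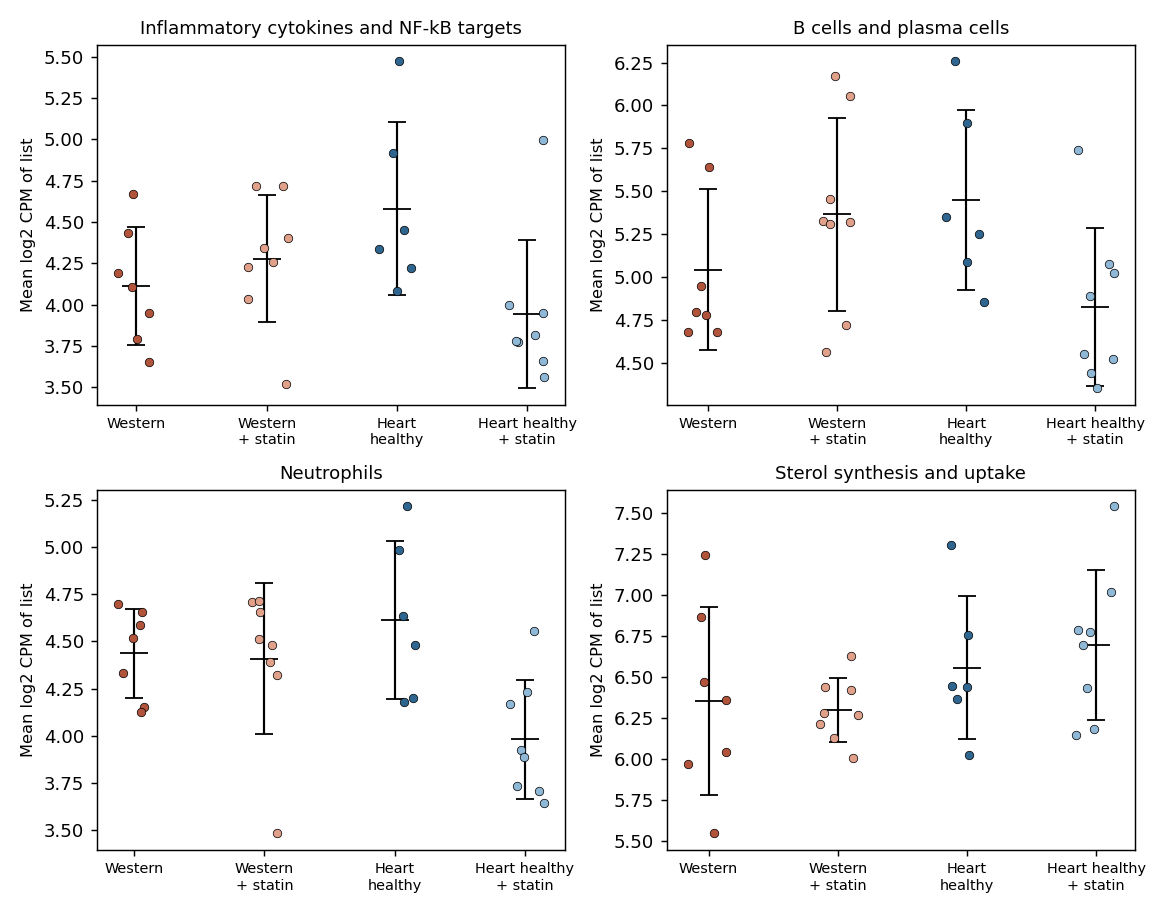
Mean log2 CPM of 4 gene lists (vertical axis) in each of the 29 libraries (points) by group, with group mean and SD (bars). The heart healthy group stands above the heart healthy plus atorvastatin group for inflammatory, B cell and neutrophil genes, with overlap of single pigs in each panel.

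Exact 2-sided permutation tests of the mean of each list gave p = 0.00699 for neutrophil genes, p = 0.00966 for T cell genes, p = 0.029 for inflammatory genes, p = 0.036 for B cell genes, p = 0.04 for antigen presentation and p = 0.138 for macrophages. The smallest of these after adjustment over the 29 lists was 0.14. Fatty acid oxidation genes and PPAR targets were higher with the drug in 20 of 22 cases (median 0.13, camera adjusted p = 0.00942). So were all 7 tested ribosomal protein genes, of 24 planned (median 0.13, camera adjusted p = 0.00623). Each of these lists had adjusted p = 0.623 with an estimated correlation. The fatty acid oxidation call ended without HHD 2 (median 0.05, adjusted p = 0.112), its median was 0.08 without HHD+S 7, and the ribosomal call ended without HHD 5 (adjusted p = 0.0542). Pool medians (1 and 2) were 0.11 and 0.13 for fatty acid oxidation and 0.09 and 0.12 for ribosomal proteins. The ribosomal call ended in pool 1 (adjusted p = 0.0601) and pool 2 (0.144) and the fatty acid oxidation call in pool 2 (0.144). HMGCR had a log2 fold change of 0.24 (SE 0.16, adjusted p = 0.623), HMGCS1 0.03 (SE 0.36, adjusted p = 0.989), SQLE 0.16 (SE 0.39, adjusted p = 0.922) and LDLR 0.47 (SE 0.35, adjusted p = 0.666). The signs of HMGCS1 and SQLE turned without HHD+S 8 (-0.19 and -0.08).

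In this contrast 0 genes passed in edgeR and 741 had an unadjusted p under 0.05 (441 lower and 300 higher). The nominal count is 366.1, but with labels exchanged between groups the median was 466. Of 100 splits, the real one included, 17 reached 741. DESeq2 called 17 (16 lower and 1 higher) and limma-voom called 0. The genes with the smallest p in edgeR, not past the threshold, were SEC14L1, of a lipid-binding protein family (log2 fold change -0.41, SE 0.08, adjusted p = 0.148), the anion exchanger SLC26A6 (-0.63, SE 0.13, adjusted p = 0.148), the metalloreductase STEAP4 (-2.45, SE 0.53, adjusted p = 0.148) and L-selectin, SELL, a homing receptor of leukocytes (-1.10, SE 0.24, adjusted p = 0.148). The glycine transporter SLC6A9 followed (-1.52, SE 0.35, adjusted p = 0.153). DESeq2 called these 5 as well. The HHD mean of STEAP4 was 10.71 CPM, and 7.11 CPM without HHD 6. Leaving out HHD 3 or HHD 5 gave 7 genes in edgeR in each case, these 5 among them. Leaving out WD+S 1 gave 3 (RN7SL1, POLR2JL* and PPP2R5E), and leaving out HHD+S 1 or HHD+S 4 gave 1 (SEC14L1). Without the 3 libraries high in RN7SL1 (WD+S 1, HHD 1 and HHD 5) edgeR called 22 genes, 21 lower and 1 higher; this omission was chosen after the data were seen and is the setting with the most calls.

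The interaction asks whether the atorvastatin difference on the Western diet departs from that on the heart healthy diet. It uses the same libraries as the simple contrasts, so its list calls are not independent of theirs. Lists, but 0 single genes in edgeR, were called. The B cell list was called positive, with 24 of 25 members above 0 (median log2 difference 0.86, camera adjusted p = 4.26e-12, adjusted p = 0.297 with an estimated correlation), and so was the inflammatory list, with 34 of 36 (0.67, adjusted p = 4.26e-12, adjusted p = 0.297 with an estimated correlation). The same held for the antigen presentation list with 25 of 25 (0.45, adjusted p = 1.7e-09, adjusted p = 0.297 with an estimated correlation) and the T cell list with 30 of 34 (0.33, adjusted p = 3.58e-07, adjusted p = 0.297 with an estimated correlation). Neutrophil genes (6 of 7, 0.55, adjusted p = 0.00568, adjusted p = 0.297 with an estimated correlation, 2 past 0.05 adjusted over the list alone) and macrophage genes (22 of 25, 0.32, adjusted p = 0.00072, adjusted p = 0.39 with an estimated correlation) went the same way. CSF3R had an interaction of 2.34 (SE 0.67; HHD mean 19.73 CPM, 12.28 without HHD 6), IRF4 of 0.85 (SE 0.26) and CTLA4 of 1.53 (SE 0.51). Interferon response genes (30 of 36, 0.38, adjusted p = 0.0047) and proliferation genes (12 of 18, 0.19, adjusted p = 0.0239) were also positive, each with adjusted p = 0.728 with an estimated correlation. CXCL11, of the interferon list, was its 1 member past 0.05 adjusted over the list alone (2.68, SE 0.70). The interferon call ended without WD+S 8 (median -0.22) or HHD 6 (-0.09), at adjusted p up to 0.651, and its median was 0.88 without WD 7 and 0.62 without HHD+S 7. The proliferation call ended without any 1 of WD 2, WD 3, WD+S 7, HHD 6 or HHD+S 2, 3, 5 or 7 (adjusted p up to 0.208). Its medians were 0.30, 0.29, 0.04, 0.12 and 0.40 without WD 7, HHD 1, HHD 6, HHD+S 3 and HHD+S 8. In pools 1 and 2 the interaction medians were 0.34 and 1.15 for B cells, 0.40 and 1.17 for inflammatory genes and 0.49 and 0.46 for antigen presentation. The other pool medians were 0.25 and 0.38 for T cells, 0.50 and 1.02 for neutrophils, 0.31 and 0.41 for macrophages, 0.19 and 0.33 for interferon genes and 0.28 and 0.08 for proliferation. In pool 2 the interferon (adjusted p = 0.2) and proliferation calls (0.417) ended.

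The endothelial list (13 of 13 members below 0, median -0.32, adjusted p = 9.89e-05, adjusted p = 0.297 with an estimated correlation) and the enteric neuron and glia list (10 of 10, -0.61, adjusted p = 0.00233, adjusted p = 0.39 with an estimated correlation) were called negative. So were the adipocyte list (7 of 7, -1.19, adjusted p = 0.0047, adjusted p = 0.387 with an estimated correlation), the colonocyte list (21 of 23, -0.16, adjusted p = 0.0269, adjusted p = 0.39 with an estimated correlation) and the sterol list (22 of 23, -0.32, adjusted p = 0.0469, adjusted p = 0.728 with an estimated correlation). Among sterol genes the interaction was -0.32 (SE 0.22) for HMGCR, -0.33 (SE 0.51) for HMGCS1, -0.34 (SE 0.54) for SQLE and -0.79 (SE 0.48) for LDLR, with adjusted p of 0.775, 0.921, 0.927 and 0.761. The sterol call ended without any 1 of WD 1, 3 or 7, WD+S 1, 4, 5, 6 or 7, HHD 1, 3, 4 or 5 or HHD+S 1, 4, 6 or 8 (adjusted p up to 0.629). Its median was -0.12 without HHD+S 8, -0.15 without WD 3, -0.21 without HHD 5 and -0.54 without HHD 6. Without WD 6 the adipocyte median was -0.77 and the neuronal median -0.30. The effect of leaving out WD 2 and WD 6 together was not tested. The colonocyte call ended without HHD 2 (median -0.09) or HHD+S 1, 4, 6 or 7 (adjusted p up to 0.0919). Pools 1 and 2 had medians of -0.39 and -0.27 for endothelium, -0.88 and -0.48 for neurons, -2.55 and -0.58 for adipocytes, -0.18 and -0.17 for colonocytes and -0.31 and -0.49 for sterol genes. The sterol call ended in pool 1 (adjusted p = 0.105) and the colonocyte (0.301), adipocyte (0.312) and neuron calls (0.346) in pool 2. Without the 3 libraries high in RN7SL1, a test chosen after the data were seen, the sterol call ended (median -0.16, adjusted p = 0.742).

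For the interaction 0 genes passed in edgeR, 520 had an unadjusted p under 0.05, DESeq2 called 1 (CLEC4G) and limma-voom 0. The smallest p belonged to RN7SL1, the RNA of the signal recognition particle (log2 interaction 12.40, SE 2.43, adjusted p = 0.118), POLR2JL* (12.18, SE 2.44, adjusted p = 0.118) and PPP2R5E, a subunit of protein phosphatase 2A (9.12, SE 1.93, adjusted p = 0.158). Next came CLEC4G (5.87, SE 1.29, adjusted p = 0.174; 4.33 without WD+S 5) and LOC110257199 (3.63, SE 0.85, adjusted p = 0.301; 1.93 without HHD 5). RN7SL1, POLR2JL* and PPP2R5E were far above the rest in 3 libraries. PPP2R5E reached 68638 CPM in HHD 5, 20355 CPM in WD+S 1 and 2275 CPM in HHD 1, against at most 550.5 CPM in the other 26. Without these 3 libraries the interactions of RN7SL1 and PPP2R5E were -0.17 and -0.40. LOC110257199 was also highest of its group in HHD 5 (27.73 CPM) and in WD+S 1 (7.37 CPM), so its interaction may not be separate from theirs.

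**Figure D4:**
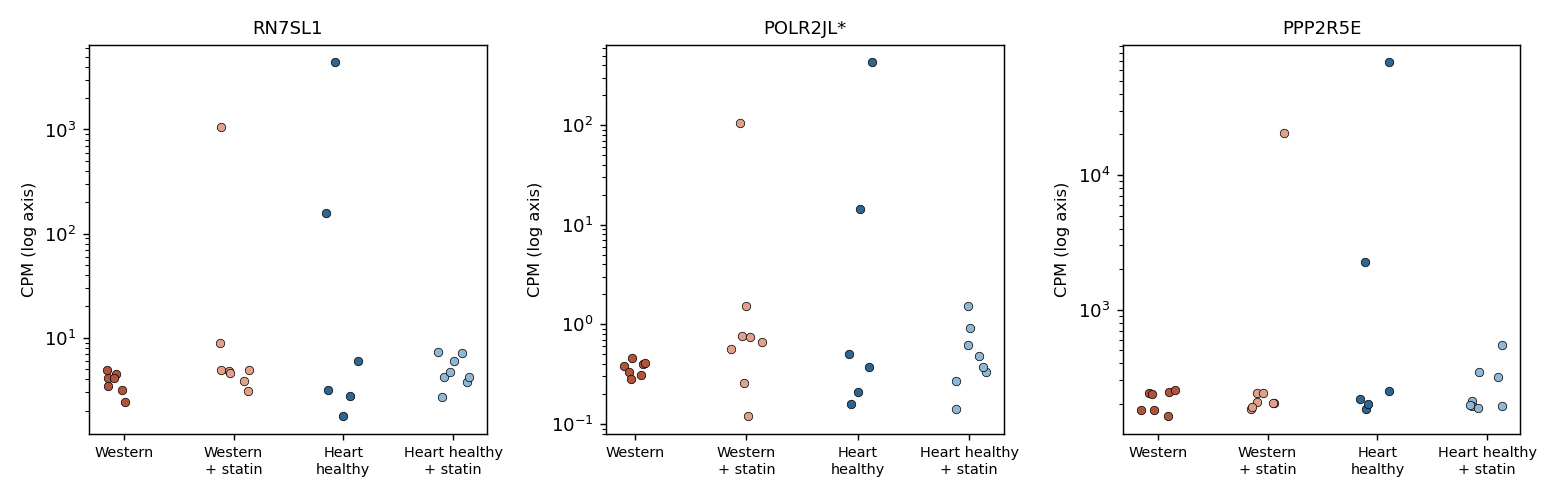
CPM of RN7SL1, POLR2JL* and PPP2R5E (vertical log axes) in each of the 29 libraries (points) by group. The same 3 libraries, HHD 5, HHD 1 and WD+S 1, stand above the rest in each panel.

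Averaged over the drug, 0 genes differed between the diets in edgeR (155 at an unadjusted p under 0.05; DESeq2 0, limma-voom 0). Averaged over the diets 0 genes differed with atorvastatin (436 at an unadjusted p under 0.05; DESeq2 0, limma-voom 0). For the average diet difference 10 lists were called with the preset correlation (7 without WD 3, WD 6, WD+S 7 or HHD+S 3), with all 23 sterol genes lower on the Western diet (median -0.32, adjusted p = 5.31e-17, adjusted p = 0.357 with an estimated correlation). Genes of bile acid and xenobiotic handling (15 of 19 higher, median 0.17, adjusted p = 0.00953, adjusted p = 0.602 with an estimated correlation, with 2 lower members past 0.05 adjusted over the list alone) and smooth muscle genes (5 of 5 higher, median 0.15, adjusted p = 0.0143, adjusted p = 0.645 with an estimated correlation) were called in this contrast alone. The sterol median was 0.00 in pool 1, where the call ended (adjusted p = 0.673), and -0.71 in pool 2. The bile acid list had 0.17 in pool 1 (call ended, adjusted p = 0.355) and 0.27 in pool 2, and its call ended without HHD 6, HHD+S 3 or HHD+S 8 (adjusted p up to 0.17). Bile acid medians were 0.09, 0.10, 0.11, 0.27, 0.09 and 0.09 without WD 4, WD+S 5, WD+S 8, HHD 5, HHD 6 and HHD+S 3. The smooth muscle list had 0.19 and 0.11 in pools 1 and 2, called in 0 of them (adjusted p = 0.0562 and 0.105). Its call ended without WD 3, WD 6, WD+S 7 or HHD 6 (adjusted p up to 0.157), with medians of 0.07, 0.10 and 0.23 without WD 6, HHD 6 and HHD+S 3. For the average atorvastatin difference 11 lists were called (7 without HHD 2 or HHD+S 7), with heat shock genes lower in 17 of 18 cases (median -0.32, adjusted p = 3.11e-06, adjusted p = 0.691 with an estimated correlation; -0.34 and -0.22 in pools 1 and 2, and called without each library). For the average diet difference HMGCR had a log2 fold change of -0.11 (SE 0.11), HMGCS1 -0.49 (SE 0.25), SQLE -0.52 (SE 0.27) and LDLR -0.26 (SE 0.24), all with adjusted p = 1. For atorvastatin HMGCR had 0.08 (SE 0.11), HMGCS1 -0.14 (SE 0.25), SQLE -0.01 (SE 0.27) and LDLR 0.08 (SE 0.24), with adjusted p of 0.922, 0.954, 0.999 and 0.982. The signs of HMGCS1, SQLE and LDLR turned when single libraries were left out. Mast cell and eosinophil, enteroendocrine, immediate early, NRF2 and oxidative stress, and sex chromosome lists were called in 0 contrasts, with smallest camera adjusted p of 0.421, 0.264, 0.0698, 0.709 and 0.752. The erythrocyte list had 1 tested member and was not tested.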

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

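In this part the counts of genes past the threshold over relabelled splits, the ratio between 3 genes, the share of a group's libraries, all 8 immune lists set against stromal ones and the difference of the colonocyte list were tests chosen after the result was seen, and the other tests were written down before their result was seen. Among the latter, the bound for rejecting an explanation was met for structural RNA and for the 2 fold correlations given among the other observations. It was also met for the sterol tests without HHD+S 8 and with the colonocyte covariate. A further requirement, that the margin exceed the spread, was added after the values were seen, so these tests are reported as open.

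Over 51 measures (25 named genes, 22 called lists and 4 library measures) in 4 groups, 204 groups of values were searched for a library standing apart, and 17 were found. Chance gives about 1 in 20 such groups, so a large part of the 17 is what chance alone gives. WD+S had 9 of them, WD 3, HHD+S 3 and HHD 2. Among genes, WD 3 was highest for SERPINB5 (158.8 CPM, others up to 86.0) and CXCL14 (1031 CPM, others up to 656.7), WD+S 5 for CLEC4G (33.02 CPM) and WD+S 8 for CXCL11 (100.5 CPM). WD+S 1 was highest for RN7SL1 (1051 CPM), POLR2JL* (104.2 CPM), PPP2R5E (20360 CPM) and LOC110257199 (7.37 CPM), and HHD 5 was highest for LOC110257199 (27.73 CPM). Among mean log2 CPM of lists, inflammatory genes were highest in HHD+S 2 (4.993), oxidative phosphorylation in HHD+S 8 (9.231), interferon genes in WD 7 (7.345) and in WD+S 8 (8.02), and heat shock genes in WD+S 1 (9.192). Neutrophil genes were lowest in WD+S 7 (3.482) and fibroblast genes in HHD 6 (7.236). HHD+S 7 had the most reads of its group (21.35 M).

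The atorvastatin difference departed between the diets for 13 lists in camera's interaction test with the preset correlation, and for 0 with an estimated one. Adjusted p was 4.26e-12 for B cells, 4.26e-12 for inflammatory genes, 1.7e-09 for antigen presentation, 3.58e-07 for T cells, 9.89e-05 for endothelium, 0.00072 for macrophages, 0.00233 for neurons, 0.0047 for adipocytes, 0.0047 for interferon genes, 0.00568 for neutrophils, 0.0239 for proliferation, 0.0269 for colonocytes and 0.0469 for sterol genes.

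RN7SL1, POLR2JL* and PPP2R5E were far above the other 26 libraries in HHD 5, WD+S 1 and HHD 1. The excess of PPP2R5E and of POLR2JL* per excess of RN7SL1 differed by at most 1.43-fold between these libraries, so 1 RNA whose reads are shared between the 3 genes is a candidate explanation. Whether diet or atorvastatin had a part stays open. At most 33.3% of a group's libraries were above 10 times the median. The bound asked for most libraries of a group, which 3 libraries could not give in groups of at least 6, so it decides nothing. A general excess of RNA without a poly(A) tail stays open: summed CPM of 166 small structural RNA genes was 121 in HHD 5 and 27.5 in WD+S 1, above the other libraries (13.6 to 27.2), and 18.9 in HHD 1, so 1 of the 3 was not above the rest. The gain such an excess would bring in HHD 1 (3.62 CPM) is within the spread of the other libraries, so that library could not decide.

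On the heart healthy diet 6 immune and inflammatory lists were called lower with atorvastatin. HHD 6 as the whole cause is argued against for the mean of the 6 called lists. It was -0.416 without HHD 6 against -0.447 with it (jackknife SE 0.168). With the preset correlation 6 of 6 lists stayed called. These lists were chosen with HHD 6 included, and a part played by it stays open. Without it the inflammatory median was -0.27 against -0.42 and the neutrophil median -0.45 against -0.72, while the macrophage median was -0.36 against -0.21. A lower share of epithelium in the heart healthy samples stays open. The bound written before (0.2 log2 apart from the stromal lists, p under 0.05) was met by the 6 called lists (-0.561, exact 2-sided permutation p = 0.025), but these were chosen for being lower. All 8 immune lists, called or not, gave -0.472 (exact 2-sided permutation p = 0.0683), with the stromal lists at 0.114 (SE 0.181). The colonocyte list was higher with atorvastatin by 0.139 (SE 0.116), the direction that a lower share of epithelium without it would give. A difference in immune cell content or activity between the groups stays open as a hypothesis, untested. So does chance: 62 of 100 splits of the labels, the real one included, called as many lists.

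Sterol synthesis and uptake genes were lower on the Western diet among atorvastatin-treated pigs. HHD+S 8 as the cause stays open: without it the median was -0.293 (jackknife SE 0.167) against -0.528, next to the bound of -0.264. A different share of colonocytes, as a part of the cause or all of it, stays open. The mean score of the colonocyte list differed by 0.022 (SE 0.099), not in the direction of the sterol list (-0.398, SE 0.175). Without HHD+S 8 these were -0.041 (SE 0.084) and -0.278 (SE 0.142). With HHD+S 8 included, sterol minus colonocyte scores differed by -0.42, with an exact 2-sided permutation p of 0.0503. With the colonocyte score as a covariate the median was -0.472 (jackknife SE 0.249, camera adjusted p = 2.7e-15). That median passed the bound of -0.264 by less than its SE. A diet effect on sterol genes may also account for it and was not separated from these. Chance stays open too. Camera with an estimated correlation gave the list an adjusted p of 0.151, and the smallest exact permutation p after adjustment over the lists was 0.258.

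Labels were exchanged between groups in 100 splits per contrast, the real one included, to ask whether chance can be excluded. For genes past the threshold the real count of 0 was reached by 100 splits in each contrast, and the highest other split called 202 for diet without atorvastatin, 8 for diet with atorvastatin, 44 for atorvastatin on the Western diet, 33 for atorvastatin on the heart healthy diet, 12 for the interaction, 1 for the average diet and 8 for the average atorvastatin difference. The split that called 33 had a correlation with pool of 0.417, against 0.125 for the real one, but splits with a higher one (up to 0.75) called 0. Splits that call many genes where the real one calls 0 may point to a structure of the samples other than the groups, which was not tested. Of 99 relabelled splits, in the same order, 5, 1, 2, 5, 1, 6 and 8 called any gene, about the share that the threshold allows. For genes at an unadjusted p under 0.05, in the same order, 38 splits reached the real 445 (highest other 1474), 89 reached 192 (1264), 68 reached 218 (915), 17 reached 741 (1607), 23 reached 520 (1384), 92 reached 155 (1393) and 37 reached 436 (1405). For lists called with the preset correlation, 67 reached 8 (highest other 17), 4 reached 13 (14), 12 reached 13 (16), 62 reached 8 (17), 11 reached 13 (16), 35 reached 10 (17) and 25 reached 11 (16). The 7 real counts of 0 are reached by any split and say nothing on chance. Of the other 14 counts, 1 was reached by fewer than 5 in 100 splits, the lists of diet with atorvastatin. About 1 in 20 counts would fall so by chance, so over the 14 chance cannot be excluded, and that count was 10 to 15 with each library left out and 0 with an estimated correlation. A relabelled split called a median of 8 to 9 lists.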

How the results depend on the processing

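Alternatives with the 3 RN7SL1-high libraries left out, fry, permutation of list scores, a Y-linked covariate, and other scalings or left-out libraries for lists were tests chosen after the data were seen. Of 2099 values of 53 named genes under alternatives, 2034 kept their direction. Of 2736 camera values (preset correlation) of 76 called lists 2500 kept camera's direction and the call, 228 lost the call and 8 turned. Lost or turned were 22 calls in pool 1, 33 in pool 2 and 169 of 2204 with 1 library left out. For simple contrasts, the 2204 include fits without a library of a group not compared. Those bear on a call only through the shared fit, which raises the share kept, also for gene values and for the list medians below. With an estimated correlation 76 of 76 calls were lost, with fry 76 of 76 and with exact permutation 42 of 42. Other scalings moved the median gene by under 0.03 log2. The cause was not tested for any change below.

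Counts of genes past the threshold, 0 in edgeR in 7 contrasts, stayed 0 with other scalings, no filter, a pool term, each pool alone, only the groups of a contrast, the Y-linked covariate, limma-voom, a threshold of 0.1 and a 1.2-fold minimum. DESeq2 called 2 for diet with atorvastatin, 17 for atorvastatin on the heart healthy diet and 1 for the interaction. Without the RN7SL1-high libraries 22 were called for atorvastatin on the heart healthy diet. Leaving out each library gave 0 to 3 for diet without atorvastatin, 0 to 1 for diet with it and 0 to 7 for atorvastatin on the heart healthy diet.

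Lists called numbered 0 in all 7 contrasts with an estimated correlation (0, 0, 0, 0, 0, 0 and 0) and with fry, and 0 in the 4 simple contrasts with exact permutation. Pool 2 alone gave 5 for diet without atorvastatin (8 in all libraries), 7 for atorvastatin on the Western diet (13) and 7 for the average atorvastatin difference (11), and leaving the RN7SL1-high libraries out gave 14 for diet without atorvastatin. That omission also ended 9 of 76 calls (adjusted p): oxidative phosphorylation for diet without atorvastatin (0.23), sterol efflux (0.0731) and goblet cells (0.0722) for diet with it, T cells (0.0611) and adipocytes (0.0616) for atorvastatin on the Western diet, ribosomal proteins on the heart healthy diet (0.138), sterol genes for the interaction (0.742), and interferon (0.361) and endothelial genes (0.211) for the average diet. Of medians of called lists it moved by over 1.5 times sterol (-0.32) and antigen presentation (-0.37) for diet without atorvastatin, transport (0.07) for diet with it, fatty acid oxidation (0.21) and macrophages (-0.32) for atorvastatin on the heart healthy diet, sterol (-0.16), proliferation (0.39), interferon (0.64) and endothelium (-0.50) for the interaction, and bile acid (0.28), T cells (-0.10), smooth muscle (0.25) and endothelium (-0.05) for the average diet. Leaving out each library gave 8 to 14 for diet without atorvastatin (14 without WD 1, WD 7 or HHD 3), 8 to 16 for atorvastatin on the Western diet (8 without WD+S 8) and 7 to 16 for the average atorvastatin difference (7 without HHD 2 or HHD+S 7).

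Medians changed sign in 16 of 2508 values: interferon genes in 3 contrasts without WD+S 8 (-0.08, -0.15 and -0.22) and in the interaction without HHD 6 (-0.09), sterol genes for diet without atorvastatin in pool 1 (0.12) and without HHD 6 (0.02), and, for diet with atorvastatin, inflammatory (-0.08), macrophage (-0.06), transport (-0.02) and sterol efflux genes (-0.004) in pool 1 and transport genes without HHD+S 3 (-0.01). The others were inflammatory genes in pool 2 (0.01) and endothelium in pool 1 (0.01) for the average diet, and T cells without WD 1 (0.002), inflammatory genes in pool 1 (0.05) and goblet cells in pool 2 (0.03) for the average atorvastatin difference. Camera directions that turned, with adjusted p, were in pool 1 alone sterol genes for diet without atorvastatin (0.592) and, for diet with it, sterol efflux (0.995) and macrophages (0.995), and in pool 2 alone antigen presentation for diet without atorvastatin (0.853) and adipocytes for atorvastatin on the Western diet (0.899). For the average diet they were inflammatory genes in pool 2 (0.535) and endothelium in pool 1 (0.969), and for the average atorvastatin difference inflammatory genes in pool 1 (0.446). With log2 fold changes, and none of these genes past the threshold, the turns for diet without atorvastatin were RN7SL1 0.17, POLR2JL* 0.21, HMGCR -0.0481 and LDLR -0.0015 without the RN7SL1-high libraries, HMGCR -0.22 and LDLR -0.34 in pool 2, HMGCS1 0.21 and SQLE 0.0447 in pool 1, and HMGCR -0.0284 and LDLR -0.36 in limma-voom. For atorvastatin on the Western diet they were HMGCR 0.18 and LDLR 0.0651 in pool 2, and HMGCR 0.0656, HMGCS1 0.40, SQLE 0.50 and LDLR 0.37 in limma-voom. For atorvastatin on the heart healthy diet they were HMGCS1 -0.10 in pool 1 and, without the RN7SL1-high libraries, HMGCS1 -0.20 and SQLE -0.0329. For the interaction they were RN7SL1 -0.17, POLR2JL* -0.0020 and PPP2R5E -0.40 without the RN7SL1-high libraries, and HMGCS1 0.0748 and SQLE 0.0901 in limma-voom. For the average diet they were HMGCR 0.0722 and LDLR 0.1425 in pool 1. For the average atorvastatin difference they were HMGCR -0.1129 and LDLR -0.2528 in pool 1, HMGCS1 0.0971 and SQLE 0.0815 in pool 2, HMGCS1 0.3577 and SQLE 0.4549 in limma-voom, and SQLE 0.0056 with upper-quartile scaling and 0.0289 with the Y-linked covariate.

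Leaving out each library moved the log2 fold change, for diet without atorvastatin, of HMGCR from -0.0858 to 0.16, HMGCS1 from -0.77 to 0.0202 and LDLR from -0.33 to 0.32. For atorvastatin on the Western diet the ranges were -0.15 to 0.0626 for HMGCR, -0.44 to 0.14 for HMGCS1, -0.36 to 0.0813 for SQLE and -0.46 to 0.15 for LDLR. For atorvastatin on the heart healthy diet they were -0.19 to 0.37 for HMGCS1 and -0.0798 to 0.48 for SQLE, and for the interaction -0.68 to 0.10 for HMGCS1. For the average atorvastatin difference they were -0.2495 to 0.0865 for HMGCS1, -0.1313 to 0.1492 for SQLE and -0.0661 to 0.3144 for LDLR. At 10531370 to 21349602 reads per library, genes near the filter, CLEC4G among them, rest on few reads.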

Other observations

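Both tests in this part were written down before their result was seen; the requirement that a negative correlation also lie outside the relabelled splits was added after the values were seen.

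The diet difference without atorvastatin was set against that with it across 7322 genes, which are not independent replicates. The Pearson r was -0.251, the opposite of what a diet effect shared by pigs with and without the drug would give. But 8 of 100 splits, the real one included, gave an r as low, and the highest other split gave 0.386. A shared effect could therefore not be excluded. The atorvastatin differences on the 2 diets had an r of -0.225, with 9 of 100 splits, the real one included, as low and 0.402 as the highest other. An atorvastatin effect shared by the diets likewise stays open.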
